A study of Danio rerio with 2 samples.

How the data were processed

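The data were CEL-seq counts of single 12 µm cryosections, taken from the injury toward the uninjured remote muscle of 1 cryoinjured adult zebrafish ventricle at 3 days post injury (dpi) and of 1 at 7 dpi. Both sample titles read WT, taken as wild type. Per the labels' protocols, RNA was extracted with TRIzol and libraries were sequenced as paired 75 bp reads on a NextSeq. Per the submitters' processing notes, reads were aligned with BWA 0.6.2. The genome build, the annotation and any use of molecular identifiers were not given in the sources used here. The deposited values, 1 table per heart with a column per section, are whole-number counts per Ensembl gene ID, not normalized, and every value was checked to be a whole number of at least 0. The unit of these columns is entered as other, because their names are bare section numbers that the automatic test of units could not read, so that test did not examine them. Section numbers were taken as the order from the injury outward that the labels' protocols describe. Columns of other samples numbered 0.

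The 3 dpi table had 16476 gene rows, of which 732 were 0 throughout, and the 7 dpi one had 16115, of which 24 were. Spike-in rows, 19 and 44, held 171 and 8631 counts and stayed out of library sizes and comparisons. Gene symbols came from a table pairing IDs with names, which named 13441 and 13135 of the IDs. The ID of highest count at 3 dpi, ENSDARG00000080337, held 20.65% of its counts and 3.6% at 7 dpi, and ENSDARG00000077505 held 6.534% at 7 dpi and 0.02325% at 3 dpi. Neither has a name in that table. Genes with a row in both tables numbered 14452, with 2024 in the 3 dpi table only and 1663 in the 7 dpi table only.

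A section was kept when its total reached 20% of the 75th percentile of section totals of its heart, a minimum of 24571 counts at 3 dpi and 16192 at 7 dpi. At 3 dpi sections 2 to 6 were left out, and at 7 dpi sections 4, 6, 9, 15, 24, 25, 27, 28, 29, 33 and 35 to 38. Kept sections held 39495 to 302404 counts at 3 dpi (median 98915; 3214 to 9864 genes detected) and 20832 to 813848 at 7 dpi (median 66331; 2408 to 11501 genes detected), which were 98.2% and 96.6% of all counts.

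Domains came from a least-squares division of the kept sections into 3 contiguous segments of at least 4 sections, on z-scored log2(CPM + 10) of the 2000 highest-mean genes that are in no fixed list. For each gene outside the lists, domains came from the 1 of 2 random sets of those genes that did not hold it. Both sets gave the same domains at 3 dpi. At 7 dpi the genes of 1 set were measured on sections 1 to 10, 11 to 16 and 17 to 34. Counts were summed per domain and given per 1000000 of the domain's gene counts (CPM), with a pseudocount of 1 CPM for log2 ratios. Median-of-ratios scaling, an alternative, took its factors from all genes with counts in every domain, or in both hearts, without a count minimum. A gene was counted in a domain when it was at least 2-fold above each of the other domains, among genes with at least 50 counts in that heart (4784 and 4608 genes, of which 4166 and 4027 were named). The count that flat profiles give from counting error was the mean of 20 Poisson draws. These draws lack the piling of a gene's counts in 1 section that the real tables show, so flat genes can give more. Folds have exact 95% Poisson intervals of the counts, and for 0 counts a floor of 3 counts over the domain. Reads without molecular identifiers are not independent molecules, so these cover counting error only.

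No test between groups was made, since there was 1 heart per day and sections of a heart are not replicates. Each of 26 gene lists fixed before the data were examined, 8 of them cell type markers and 18 pathways, was summarised by its median log2 difference and the percentile of that median among 10000 random lists of the same size matched on expression in 20 bins. Genes were treated as independent in drawing these lists, so a percentile describes these libraries only. A list needed 3 measured members, and lay outside its matched range under percentile 2.5 or over 97.5. The lists were contractile, stress-responsive cardiomyocyte, leukocyte, inflammation, matrix, epicardium, endothelium, erythrocyte, smooth muscle and valve (with outflow tract), atrium, nerve and glia, oxidative, glycolysis, cell cycle, BMP ligands, BMP receptors and Smads, BMP targets, BMP antagonists, TGF-beta and activin, Notch, retinoic acid, growth factors (neuregulin, EGF, FGF, PDGF, VEGF and IGF), Jak/Stat, Wnt with Hippo and Hedgehog, ribosome and mitochondrial genome. List members were zebrafish symbols, while many IDs carry symbols in capitals: matching ignored case, and a capital symbol also matched a member without its final a or b. This matching was chosen after the gene names were seen, and it can bring several paralogs under 1 symbol, so IDs stand beside duplicated symbols where needed.

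Comparisons were of domains within each heart, of domain genes between hearts, of 7 against 3 dpi over all kept sections and by domain, and of BMP pathway genes with at least 20 counts along the axis, with the 5-section running window of highest level. Named genes followed a rule fixed before the data were examined. For each domain it took the 8 genes of highest value in the lower of the 2 hearts and the 2 of highest value in 1 heart only, for the days the 8 highest and 8 lowest ratios, and for each list up to 4 members of largest difference. Symbols that are clone or locus names were left out, and some genes that the rule names are not reported here. NDUFB9 is among the examples of its list. The share of a named gene's counts held by its top section was computed after seeing the data.

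The analysis was run on simulated data first: in tables with known domains, 86.9% of genes set 3-fold higher in a domain were recovered at the 3 dpi depths and 90.0% at the 7 dpi depths, 97.0% of 4-fold genes at each, and 24 of 1595 and 27 of 1433 flat genes were called. The simulated counts were Poisson draws, without the piling of a gene's counts in 1 section that the real tables show. These rates therefore do not describe calls made from such genes. The alternatives numbered 11 planned (section minimum, gene minimum, scaling, domain definition, pooling and pseudocount) and 8 added after seeing the data: no section 34 at 7 dpi, no section 1 at 3 dpi, no top 2 unnamed IDs, counts thinned to equal totals, levels raised to at least 3 counts per domain or heart, sections whose contractile genes sum to 30000 to 80000 CPM, the same without section 34, and each gene's section of most counts left out of its highest domain. The set of summary results compared across alternatives was shortened after a first run, by merging counts of lists above and below the matched range and summing the domain overlaps, so a shift between above and below can be hidden. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, with a random seed of 1.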

Results

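The series title names BMP signalling as a regulator of zebrafish cardiomyocyte regeneration, and the libraries measured gene expression along the axis from a cardiac injury to uninjured muscle. Zebrafish regrow heart muscle after cryoinjury, in which part of the ventricle is killed by freezing. Single 12 µm cryosections of 1 injured wild-type ventricle at 3 days post injury (dpi) and of 1 at 7 dpi were sequenced by CEL-seq, a method that tags the ends of transcripts in small RNA samples. The 3 dpi heart had 40 sections with 10842 to 302404 counts each, of which 35 were kept, and the 7 dpi heart had 38 sections with 1528 to 813848 counts each, of which 24 were kept. Kept sections held 3914252 counts at 3 dpi and 3194233 at 7 dpi, and section 34 of the 7 dpi heart alone held 25.5% of its kept counts. There was 1 heart per day, so no test between hearts was possible and no replicate error can be given. Ranges in parentheses after a fold are 95% exact Poisson intervals and cover counting error only.

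Kept sections were divided along the axis into 3 contiguous domains named by place: injury-side, middle and remote-side. At 3 dpi they spanned sections 1 to 10, 11 to 19 and 20 to 40, with 5, 9 and 21 kept sections. At 7 dpi they spanned sections 1 to 7, 8 to 17 and 18 to 34, with 5, 8 and 11 kept sections. Contractile genes summed to 21120 ± 10010, 63290 ± 16010 and 97100 ± 9877 CPM (counts scaled to a library of 1000000; mean ± SD over sections) across the 3 domains at 3 dpi. At 7 dpi the same sums were 512.2 ± 247.5, 919.0 ± 662.4 and 22180 ± 21690 CPM, and only kept sections 30, 31, 32 and 34 passed 30000 CPM. Leukocyte genes summed to 15480 ± 2975, 6279 ± 2551 and 2287 ± 834.9 CPM at 3 dpi, against 9713 ± 2468, 12970 ± 3664 and 7123 ± 3315 CPM at 7 dpi. Domains of the same name were therefore not the same tissue in the 2 hearts.

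**Figure D1:**
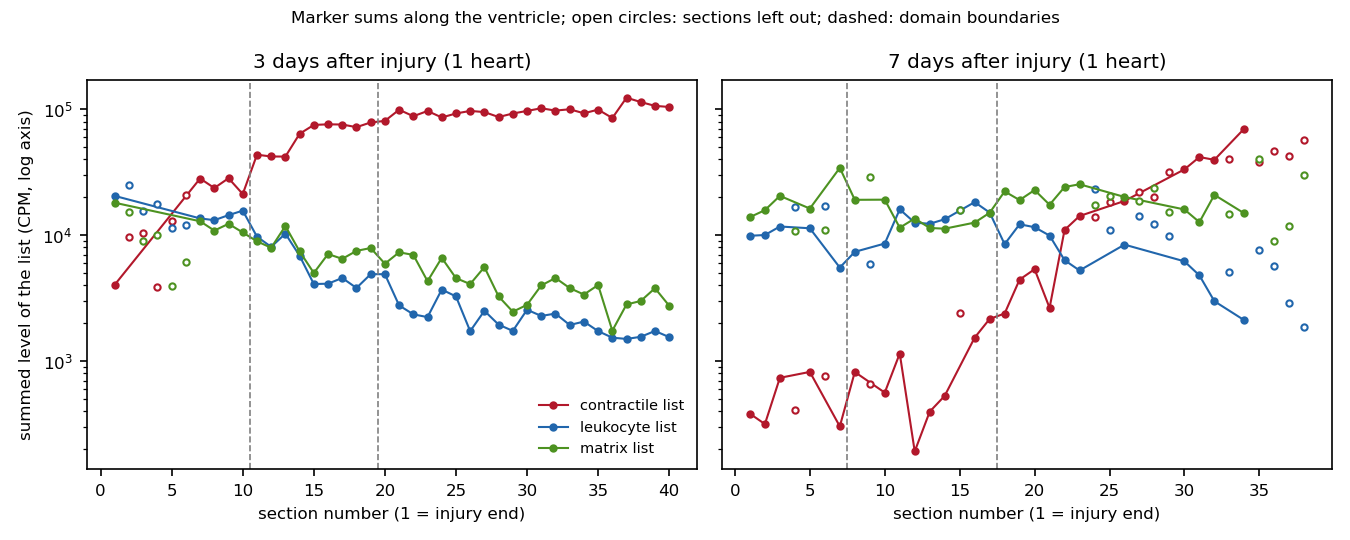
Summed level in CPM of the contractile, leukocyte and matrix gene lists in each section on a log axis, by section number from the injury outward, for the 3 dpi and the 7 dpi heart (open circles, sections left out; dashed lines, domain edges). Contractile genes averaged 97100 CPM in the remote-side domain at 3 dpi and 22180 CPM at 7 dpi.

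In the 3 dpi heart, the question was which transcripts marked the injury, the tissue next to it and the remote muscle. Leukocyte, matrix and cell division genes were higher on the injury side, and contractile and energy metabolism genes were higher on the remote side. The 27 leukocyte genes had a median injury-side minus remote-side log2 difference of 3.11, above all 10000 random lists matched on expression, and 26 of them were at least 2-fold higher on the injury side. The 26 contractile genes had a median of −2.01, below all 10000 random lists, and 24 of them were at least 2-fold lower on the injury side. Of 4784 genes, 517 were at least 2-fold higher on the injury side than in either other domain, 39 in the middle and 78 on the remote side, where counting error on flat profiles gave means of 38.2, 2.8 and 5.8.

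Among leukocyte genes at 3 dpi, the cathepsin gene ctss2.1 was 28.7-fold higher on the injury side than on the remote side (20.8 to 40.2), and HMOX1, the haem-degrading oxygenase of macrophages, was 18.5-fold higher (15.2 to 22.7). MFAP4 (ENSDARG00000088745), used as a macrophage marker in zebrafish, was 16.7-fold higher (12.1 to 23.1). The 28 matrix genes had a median log2 difference of 1.52, at percentile 99.97 of the random lists, with 20 at least 2-fold higher and 0 lower. They included the collagen gene COL11A1 at 13.5-fold (9.18 to 20.1), the fibronectin gene FN1 at 8.57-fold (7.17 to 10.2) and the metalloprotease inhibitor TIMP2 (ENSDARG00000075261) at 14-fold (10.9 to 18.1). The 33 cell cycle genes had a median of 1.29 at percentile 99.87, with 22 at least 2-fold higher and 0 lower. The mitotic genes BIRC5, ccnb3 and plk1 were 8.29-fold (4.64 to 14.7), 8.37-fold (4.48 to 15.5) and 5.60-fold (3.08 to 9.90) higher on the injury side. The 66 ribosomal protein genes had a median of 0.69 at percentile 98.97, which turned to −0.18 under median-of-ratios scaling.

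Energy metabolism ran the other way at 3 dpi. The 81 oxidative genes had a median log2 difference of −1.26 and the 24 glycolysis genes −1.47, each below all 10000 random lists, with 53 and 15 members at least 2-fold lower on the injury side and 1 higher in each list. The mitochondrial creatine kinase gene CKMT2 (ENSDARG00000039929) was 12.5-fold higher on the remote side than on the injury side (6.55 to 27.4), and GAPDH, a glycolytic enzyme gene, was 7.52-fold higher (6.71 to 8.46). The 13 genes of the mitochondrial genome had a median of −1.59 at percentile 0.06, with MT-ATP6 3.16-fold higher on the remote side (3.02 to 3.31). Among contractile genes, the skeletal-type actin gene ACTA1 was 10.1-fold (6.91 to 15.3), the myosin light chain gene MYL7 7.06-fold (6.47 to 7.72) and the troponin gene tnnc1a 6.06-fold (4.80 to 7.78) higher on the remote side. The 17 stress-responsive cardiomyocyte genes had a median of −0.37 at percentile 1.38, and the 17 endothelial genes −0.44 at percentile 0.16, which turned to 0.37 with 3 domains of equal section number and to 0.16 with a section minimum of 40%.

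The other lists at 3 dpi lay inside the matched range of their random lists. Medians were 1.19 for 10 inflammation genes, 1.09 for 15 epicardial genes, 1.16 for 3 retinoic acid genes, 1.00 for 10 Jak/Stat genes, −0.03 for 6 TGF-beta and activin genes and −0.25 for 11 Wnt, Hippo and Hedgehog genes. Single members were far higher on the injury side: the chaperone gene CLU 12.6-fold (7.0 to 22.9), the transcription factor gene CEBPB 9.15-fold (6.83 to 12.2) and ALDH1A2, the gene of a retinoic acid synthesis enzyme, 7.01-fold (5.67 to 8.66). Medians of 0.42 for 9 erythrocyte genes, 0.19 for 5 smooth muscle and valve genes, 0.11 for 3 atrial genes, 0.43 for 8 Notch genes and 0.35 for 13 growth factor genes each changed sign under median-of-ratios scaling, to −0.44, −0.67, −0.75, −0.38 and −0.50.

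In the middle domain of the 3 dpi heart, between the injury and the remote muscle, stress-responsive, cell cycle and inflammation genes lay above the mean of the other domains. The median middle minus others log2 difference was 0.44 for stress-responsive cardiomyocyte genes (percentile 99.62), 0.54 for cell cycle genes (percentile 99.98), 0.53 for inflammation genes (percentile 99.42), 0.39 for contractile genes (above all 10000 random lists) and 0.36 for mitochondrial-genome genes (percentile 98.56). The natriuretic peptide gene nppb stood at 695.1, 1303 and 408.1 CPM from the injury-side to the remote-side domain, and MUSTN1 at 857.5, 1935 and 1029 CPM. The proliferation marker mki67 stood at 34, 51.8 and 10.2 CPM. As sums, cell cycle genes averaged 2988 ± 446.8, 2494 ± 315.8 and 1189 ± 383.2 CPM over sections (mean ± SD) and inflammation genes 1437 ± 263.3, 1051 ± 253.5 and 369.2 ± 127.5 CPM, both highest on the injury side, and the stress-responsive median turned to −0.015 with 3 domains of equal section number. Contractile and mitochondrial-genome sums were highest on the remote side, at 97100 and 79720 CPM against 63290 and 62160 CPM in the middle. Erythrocyte genes were lower there, with a median of −0.93, below all 10000 random lists, and the blood cell gene hemgn stood at 90.7, 20.9 and 40.5 CPM. The ribosomal median of 0.02 lay at percentile 0.02 and was −0.03 under median-of-ratios scaling.

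The median over all genes of the 3 dpi injury-side minus remote-side log2 difference was 0.53, and −0.31 under median-of-ratios scaling, which turned the split from 517 injury-side and 78 remote-side genes to 133 and 408. Genes of few counts also entered these factors, and whether unequal domain depth moves them, and the sign changes under them, was not tested. With the 2 unnamed gene IDs of highest count left out, an alternative chosen after seeing the data, the split was 354 and 125. With each gene's section of most counts left out of its highest domain, also chosen after seeing the data, 224 of the 517, 18 of the 39 and 62 of the 78 still passed.

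In the 7 dpi heart, the same question gave a different picture, since contractile genes were low outside the last sections. The 25 contractile genes had a median injury-side minus remote-side log2 difference of −7.00, below all 10000 random lists, with 24 at least 2-fold lower on the injury side. Of these genes 15 had 0 injury-side counts, so the size of that median is set by the pseudocount of 1 CPM. With levels raised to at least 3 counts per domain, a setting added after seeing the data, it was −4.26, still below all 10000. The 31 leukocyte genes had a median of 0.98, above all 10000 random lists, with 14 at least 2-fold higher and 2 lower. The 16 endothelial genes had a median of −5.05 and the 17 stress-responsive cardiomyocyte genes −4.74, or −1.84 and −2.37 with that floor, each below all 10000 random lists. In these lists 10 and 7 genes had 0 injury-side counts. Of 4608 genes, 177 were at least 2-fold higher on the injury side than in either other domain, 331 in the middle and 629 on the remote side, where counting error on flat profiles gave 25.6, 28.5 and 13.2. Piling of counts in 1 section is again not part of those means. The middle count was 214 without section 34, and the remote-side count 405 with the floor of 3 counts.

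On the remote side at 7 dpi, the cardiac troponin gene TNNT2 had 6332 counts against 0 on the injury side, at least 170-fold higher against a floor of 3 counts over the domain. The myosin light chain gene cmlc1 was 796-fold higher (220 to 6573; 19802 against 2 counts), and 132-fold over the middle domain, or 58.5-fold without section 34. The endothelial cadherin gene cdh5 had 1440 counts against 0, and the von Willebrand factor gene vwf was at least 6.99-fold higher. The Notch-modifying glycosyltransferase gene LFNG was 71.8-fold higher (19.8 to 593; 1785 against 2 counts) and the secreted Wnt inhibitor gene SFRP5 at least 55.4-fold (2069 against 0 counts). GAPDH was 170-fold higher on the remote side (66.2 to 623), and hbaa2, an adult globin gene, 28.6-fold (9.75 to 139). The smooth muscle genes MYL9 (ENSDARG00000038123) and TAGLN (ENSDARG00000045408) were 4.68-fold and 4.66-fold higher on the remote side, and the activin subunit gene INHBB at least 5.84-fold. Section 34 held 65.9% of the remote-side counts of TNNT2, 57.4% of those of SFRP5 and 71.7% of those of GAPDH, against 32.8% of all remote-side counts.

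Besides those, 8 lists stood below their random lists at 7 dpi: oxidative genes at −1.31 and glycolysis genes at −1.91 (each below all 10000), mitochondrial-genome genes at −1.34 (below all 10000), smooth muscle and valve genes at −1.90 (percentile 0.01), erythrocyte genes at −2.0 (percentile 1.53), growth factor genes at −1.96 (percentile 2.38), Wnt, Hippo and Hedgehog genes at −1.90 (percentile 1.09) and the 3 atrial genes at −9.56 (below all 10000). The atrial list shared MYH6 and nppa with the contractile and stress lists. It had 2 members with 0 injury-side counts and lay at −5.55 with the floor of 3 counts. The erythrocyte and the Wnt, Hippo and Hedgehog medians then lay inside the matched range, at −0.64 (percentile 14.11) and −0.75 (percentile 8.52). Other medians lay inside the matched range: 0.28 for 33 matrix genes, 0.29 for 66 ribosomal genes, 0.29 for 15 epicardial genes, −0.19 for 12 inflammation genes, −0.18 for 15 Jak/Stat genes, −0.13 for 16 cell cycle genes, −1.47 for 10 Notch genes, −1.66 for 8 TGF-beta and activin genes and −1.38 for 4 retinoic acid genes. The nerve and glia list had 1 measured member, SNCG, at 3.85-fold higher on the injury side (2.09 to 6.72), with 64.7% of its injury-side counts in section 7.

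Injury-side excesses at 7 dpi differed in how many sections carried them. The largest section of that domain held 40.1% of all its counts. The macrophage gene MPEG1 (ENSDARG00000055290) was 3.54-fold higher than on the remote side (2.69 to 4.62), with 45.8% of its injury-side counts in section 5, HMOX1 3.67-fold (2.04 to 6.29), the chemokine gene ccl34b.4 6.22-fold (3.39 to 11) and the retinoid receptor gene rxrbb 2.98-fold (2.65 to 3.35), with counts of rxrbb in all 5 sections. FOSL1 had 81 injury-side counts, all in section 5, and of the 18 injury-side counts of the other MPEG1 gene (ENSDARG00000043093) 94.4% were in section 7. In the middle domain leukocyte genes had a median of 0.52 against the mean of the other domains (percentile 99.89), with the myeloid transcription factor gene spi1a at 5.01, 46.8 and 17.7 CPM and the cathepsin gene CTSD at 355.8, 669.4 and 271.9 CPM across the domains. Contractile, stress-responsive, oxidative, glycolysis and mitochondrial-genome lists lay below that mean, at −2.14, −1.44, −0.55, −0.53 and −0.66, as did the BMP antagonists at −1.37 (percentile 1.82). As sums, contractile genes averaged 512.2, 919.0 and 22180 CPM and stress-responsive genes 270.0, 333.8 and 2639 CPM over sections. Both were thus lowest on the injury side, not in the middle.

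The 7 dpi median over all genes was −0.20, and −0.28 under median-of-ratios scaling. With each gene's section of most counts left out of its highest domain, 44 of the 177 injury-side, 91 of the 331 middle and 478 of the 629 remote-side genes still passed, and the middle contractile and stress medians changed sign to 0.52 and 0.98 where sections needed 40% of the 75th percentile of section totals. The injury-side minus remote-side medians of erythrocyte and of smooth muscle and valve genes at 7 dpi also changed sign, to 0.13 and 0.14 with that minimum and to 0.46 and 1.02 with a minimum of 5%.

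**Figure D2:**
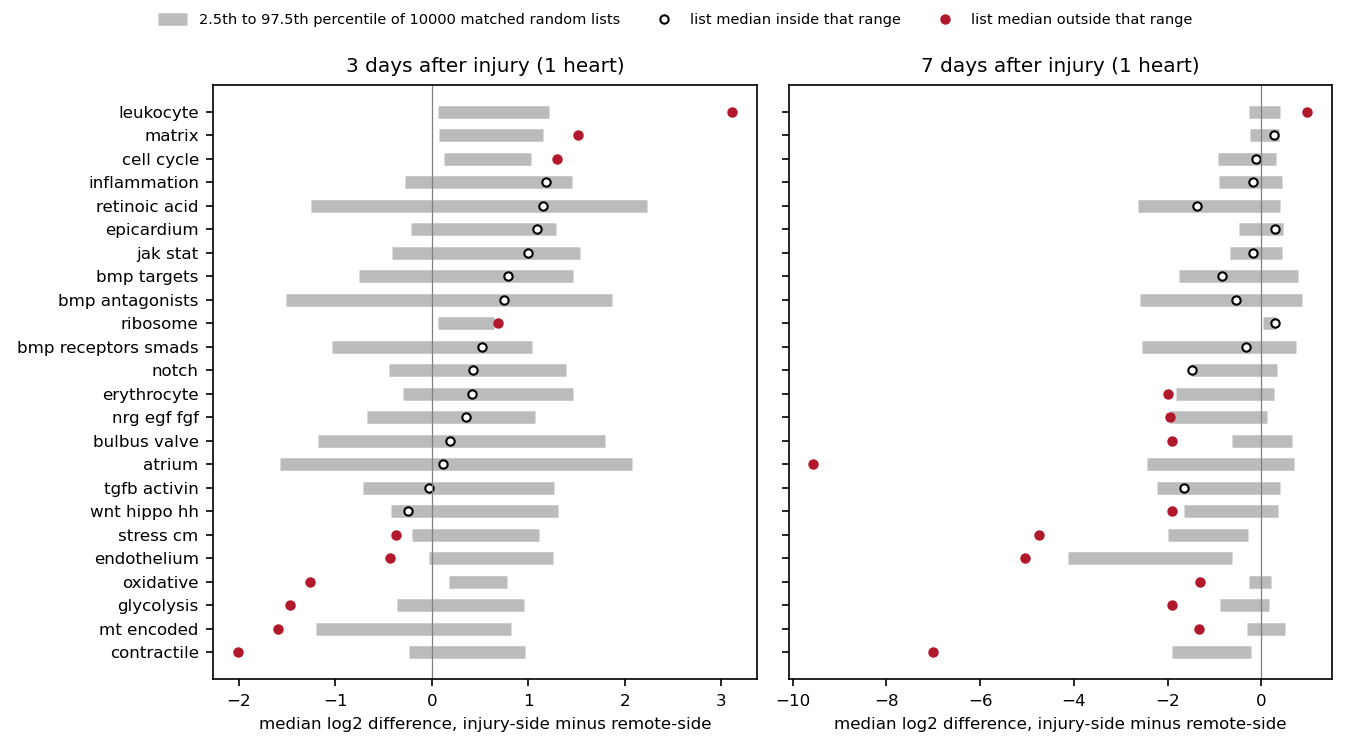
Median log2 difference between the injury-side and remote-side domains for each gene list in the 3 dpi and the 7 dpi heart, with the range of matched random lists. Leukocyte genes lay at 3.11 and 0.98 and contractile genes at −2.01 and −7.00 (−4.26 with levels of at least 3 counts, since 15 of the 25 genes had 0 injury-side counts at 7 dpi), while erythrocyte, smooth muscle and valve, atrial, BMP, Notch, growth factor and ribosomal medians at 3 dpi change sign under median-of-ratios scaling.

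The next comparison asked which genes had the same domain in both hearts, which share no libraries. Contractile genes were lower on the injury side of both. Among 3497 genes measured in both, 37 were at least 2-fold higher in the same domain of both hearts where 17.3 were expected from the separate counts. They were 19 remote-side genes (4.0 expected), 16 injury-side genes (12.1 expected) and 2 middle genes (1.2 expected). This number moved by more than 1.5 times under 10 of 16 alternatives, among them 135 under median-of-ratios scaling, 87 with 4 segments, 72 with thinned counts and 23 without section 34. No expected number was computed for the alternatives, and it grows with the number of genes called in each heart. The injury-side genes of 3 dpi were shared more with the middle genes of 7 dpi, 45 against 21.4 expected, and less with its remote-side genes, 18 against 61.0 expected. Across genes, which are not independent replicates, the injury-side minus remote-side log2 differences had Pearson r 0.425 and Spearman rho 0.381, with r 0.403 without contractile genes and 57.2% of genes of the same sign.

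The remote-side genes named by the rule included members of the contractile and glycolysis lists. Folds over the next domain at 3 dpi and 7 dpi were 3.35 (2.96 to 3.81) and at least 24.7 for ACTA1, 2.32 and 20.1 for CASQ2, which encodes a calcium store protein, 2.46 and 25.8 for the glycogen phosphorylase gene PYGM, 2.25 and 96.8 for GAPDH, and 2.27 and 2.81 for the phosphofructokinase gene PFKM. PDK2 gave 2.94 and 4.13, asb5b 2.71 and at least 2.2, and the AMP kinase subunit gene PRKAG2 2.68 and 19.8. Without section 34 the 7 dpi folds were 40.7 for GAPDH, 11 for CASQ2, 7.37 for PYGM, 12.3 for PRKAG2, 1.84 for PDK2 and 0.983 for PFKM. EGLN2 and BBOX1 were named at 3 dpi only, at 2.43 and 2.38, and rbfox1l and vwf at 7 dpi only, at least 25.7 and at least 6.99. The gene vwf was highest on the injury side at 3 dpi, at 64.2, 36.4 and 23.7 CPM.

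The injury-side genes named by the rule included ADISSP at 4.99-fold (2.17 to 11.9) and 2.33-fold (1.51 to 3.54) over the next domain, YTHDF2 at 2.23 and 2.32, rxrbb at 2.26 and 2.61, MGST2 at 2.57 and 8.47, and TMEM9B at 4.6 and 2.2. The inhibitor of NF-kappaB gene nfkbiaa gave 2.81 (1.71 to 4.61) and 3.24, dek 2.51 and 10.4, and the filament gene VIM 2.35 and 2.43, but without their top section the 7 dpi folds of these genes were 0.998, 0.577 and 0.903. Without their top section the 3 dpi folds of MGST2, TMEM9B, dek and VIM were 1.51, 2.79, 0.903 and 1.43. CMKLR1 and cd9b were named at 3 dpi only, at 6.86 and 6.31, and ccdc106a and TAB2 at 7 dpi only, at 9.60 and 5.86, with 89.1% and 97% of their counts in 1 section.

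Folds here carry no pseudocount, while the counts of shared genes use 1 CPM, so more genes pass 2-fold here than were counted. The middle genes named by the rule were IGF2R at 2.1-fold (1.31 to 3.32) and 2.81-fold (1.60 to 5.32), adtrp1 at 2.09 and 2.02, the cytokine signalling gene stat6 at 2.04 and 2.64, the kinase gene MAP3K7 at 1.83 and 2.60, PGAM5 at 1.85 and 2.60, U2AF2 at 1.87 and 2.04, GPBP1L1 at 1.79 and 1.85, and the calcium channel gene ORAI1 at 2.33 and 4.03. All 31 of the 7 dpi middle counts of ORAI1 were in section 14, GPBP1L1 was 0.746-fold without its top section, and U2AF2 was 1.06-fold at 3 dpi without its own. DYNC1LI2 and LMAN1 were named at 3 dpi only, at 2.82 and 2.78, and JMJD1C and CASTOR2 at 7 dpi only, at 11.5 and 9.63, the former at 4.76 without its top section and the latter from 22 counts in 1 section.

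Whole ventricles were compared to ask how the injured heart differed between 7 and 3 dpi. By list medians, matrix genes and smooth muscle and valve genes were higher in the 7 dpi heart, and contractile, energy metabolism and cell cycle genes were lower. The smooth muscle and valve list also holds outflow tract genes, so its median does not tell which tissue gave it. The 34 matrix genes had a median 7 minus 3 log2 ratio of 1.41, above all 10000 random lists, with 24 at least 2-fold higher and 2 lower, and all 8 smooth muscle and valve genes were at least 2-fold higher, with a median of 2.15 (percentile 99.71). The 27 contractile genes had a median of −1.84 and the 81 oxidative genes −1.60, each below all 10000 random lists. The lower lists were measured in sections that held less contractile transcript, 22180 against 97100 CPM on the remote side. Of 5883 genes, 1702 were at least 2-fold higher at 7 dpi, 1234 lower and 2947 within 2-fold.

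Among matrix genes, thrombospondin THBS1 stood at 10.2 CPM at 3 dpi and 313.4 at 7 dpi, the collagen cross-linking enzyme gene LOX at 8.43 and 238.6 CPM, and COL6A2 at 65.7 and 855.0 CPM, while the tenascin gene TNC stood at 20.9 and 1.57 CPM. Among smooth muscle genes, TAGLN (ENSDARG00000033466) stood at 178.3 and 1243 CPM, MYLK at 5.88 and 56.4 CPM and MYH11 at 6.90 and 43.8 CPM. The 34 cell cycle genes had a median of −0.81 (percentile 0.11), with 3 at least 2-fold higher, 10 lower and 21 within 2-fold, the replication clamp gene PCNA standing at 399.6 and 4600 CPM against this direction and NUSAP1 at 13.8 and 1.57 CPM along it. As sums, cell cycle genes ran against this median in each domain. From injury-side to remote-side they averaged 4877, 4704 and 4606 CPM over sections at 7 dpi, against 2988, 2494 and 1189 CPM at 3 dpi. PCNA alone stood at 4600 CPM over the 7 dpi heart, a level near those 7 dpi sums. The sums can therefore reflect this 1 gene rather than the list. The 24 glycolysis genes had a median of −1.16 (percentile 0.01), and the 19 stress-responsive cardiomyocyte genes −0.67 (percentile 2.12). The calcium pump gene atp2a2a stood at 1738 and 131.2 CPM and MYBPC3 at 1525 and 123.3 CPM. Leukocyte genes had a median of 0.81 (percentile 97.42), inside the matched range, with ctss2.2 at 123.1 and 758.6 CPM and HMOX1 at 199.5 and 35.7 CPM.

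The genes of largest ratio named by the rule included F13A1, a coagulation factor subunit gene, with 2 counts at 3 dpi and 11294 at 7 dpi, RIPOR2 with 18 and 1093, eslec with 13 and 728, MON1A with 13 and 699, spns2 with 5 and 647, MTHFD1L with 2 and 279, nppal with 2 and 237 and SNORA73 with 2 and 226. The genes of lowest ratio included RBP2 with 527 and 7 counts, mpped2 with 473 and 17, golm1 with 451 and 10, the adenine nucleotide carrier gene SLC25A4 with 282 and 4, RAB14 with 280 and 4, GLS2 with 229 and 3, and myot with 165 and 4. The complex I gene NDUFB9 stood at 392.2 and 16670 CPM.

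Other lists lay inside the matched range: epicardium 0.68, inflammation 0.55, endothelium 0.20, atrium 0.19, erythrocyte −0.67, TGF-beta and activin 0.82, Notch 0.59, retinoic acid 2.17, growth factors −0.24, Jak/Stat 0.89, Wnt, Hippo and Hedgehog 0.57, ribosome −0.14 and mitochondrial genome −0.60. The chemokine gene CXCL12 stood at 71.3 and 771.7 CPM and SFRP5 at 65.7 and 650.5 CPM. The median over all genes was 0.14, and −0.06 under median-of-ratios scaling, where 1474 genes were higher and 1468 lower. Sections of like contractile level, chosen after seeing the data, were the 9 of the 3 dpi middle domain and 4 remote-side ones at 7 dpi. They were sections 11 to 19 and sections 30, 31, 32 and 34, so place differs along with day. In them the matrix median was 0.42 (percentile 91.73), the smooth muscle and valve median 1.52 (percentile 96.95) and the glycolysis median 0.13 (percentile 84.13), all inside the matched range. Outside it, ribosomal genes had a median of −0.58 (percentile 0.09), oxidative genes −0.54 (percentile 0.72), cell cycle genes −1.29 (percentile 0.45), leukocyte genes −1.32 (below all 10000 random lists) and endothelial genes 1.12 (percentile 97.55). There 642 genes were higher and 565 lower. Section 34 held 61.3% of the 7 dpi counts in these sections. Without it the matrix and the smooth muscle and valve medians were 0.85 (percentile 99.91) and 1.70 (percentile 97.92), outside the range. The glycolysis median was −0.52 (percentile 21.64), leukocyte genes lay at −0.81 (percentile 5.27) and cell cycle genes at −1.47 (percentile 5.15), all inside, while oxidative genes lay at −0.83 (below all 10000), ribosomal genes at −0.59 (percentile 0.82) and 6 endothelial genes at 2.45 (percentile 99.75). Then 409 genes were higher and 545 lower.

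By place, the remote-side domain of the 7 dpi heart had higher matrix and leukocyte transcripts than that of the 3 dpi heart. There the 7 minus 3 medians were 1.80 for 27 matrix genes (percentile 99.98) and 1.43 for leukocyte genes (percentile 99.86), against −1.55 for contractile, −1.50 for oxidative, −1.62 for erythrocyte, −0.82 for stress-responsive and −0.88 for glycolysis genes. On the injury side the contractile median was −6.76, the oxidative −1.57, the glycolysis −1.83, the erythrocyte −2.95, the stress-responsive −4.39 and the atrial −8.40. There matrix genes lay at 0.29 and leukocyte genes at −0.73, both inside the matched range. With the floor of 3 counts the contractile median there was −4.10, and the glycolysis median −0.84 lay inside the range (percentile 8.73). The stress-responsive, atrial and erythrocyte medians there were then −1.41, −4.39 and −2.23. In the middle the contractile median was −6.64, the oxidative −2.20, the glycolysis −1.82, the cell cycle −1.34, the mitochondrial-genome −1.21, the stress-responsive −4.66 and the atrial −6.05 (3 genes). The floor brought the contractile and stress-responsive medians of the middle to −5.88 and −3.19. Leukocyte genes lay there at 0.81, inside the matched range (percentile 97.17). Cell cycle genes lay inside it at −1.44 on the injury side (percentile 5.35) and at 0.11 on the remote side (percentile 13.5), in the 15 genes with at least 50 counts in each heart, against 34 genes over all sections. Day, heart and the make-up of the domains cannot be separated in these values.

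**Figure D3:**
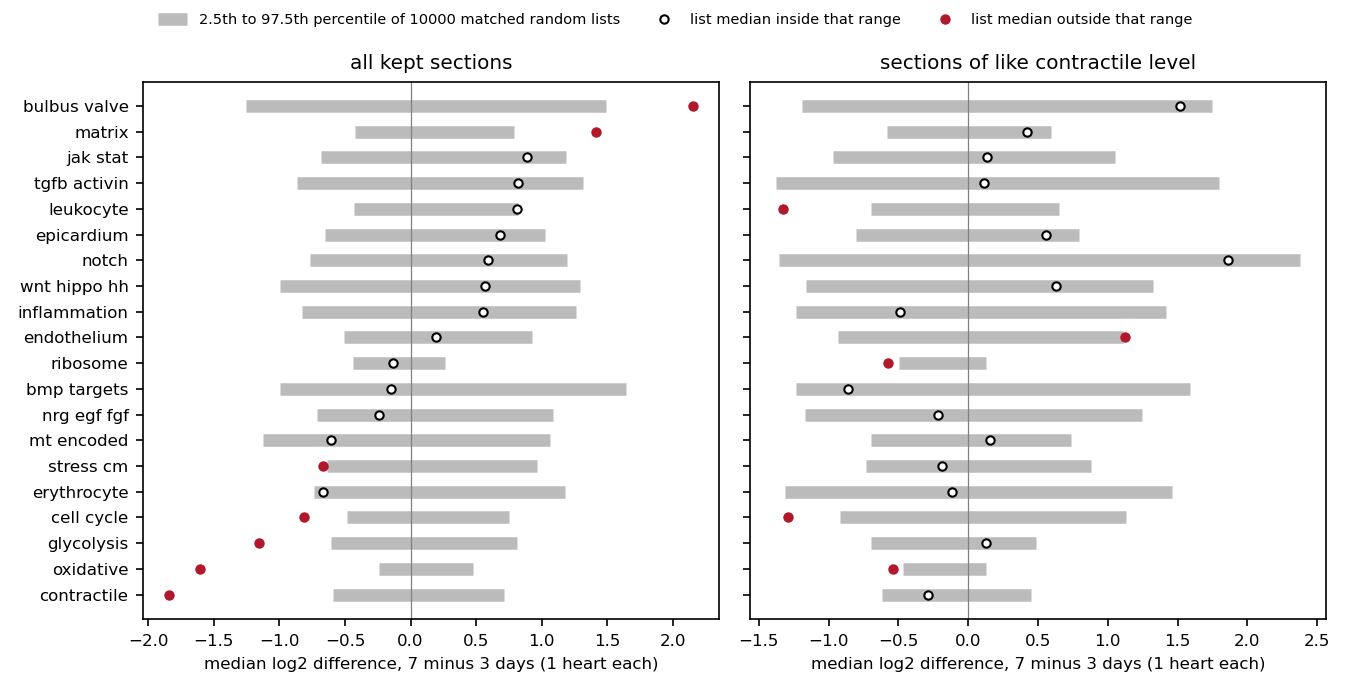
Median 7 minus 3 dpi log2 ratio of each gene list over all kept sections and over sections of like contractile level, with the range of matched random lists. Sections of like contractile level were the middle domain at 3 dpi and remote-side sections at 7 dpi, so place differs along with day. Glycolysis genes lay at −1.16 over all sections and at 0.13 in the sections of like contractile level.

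BMP pathway genes were followed along the axis because the title names the pathway. Of 22 BMP genes with at least 20 counts at 3 dpi, 12 were highest on the injury side, 7 in the middle and 3 on the remote side, or 8, 8 and 6 under median-of-ratios scaling. Of 20 such genes at 7 dpi, 3 were highest on the injury side, 5 in the middle and 12 on the remote side, or 2, 4 and 14 under that scaling. They were 8, 4 and 8 with the floor of 3 counts, which by itself can make the injury side the highest. Of all genes with at least 20 counts, 52.8%, 26.7% and 20.5% were highest in these domains at 3 dpi and 26.6%, 34.4% and 39% at 7 dpi, against 54.5%, 31.8% and 13.6% and 15%, 25% and 60% of BMP genes. Under median-of-ratios scaling the shares of all genes were 32.1%, 24.8% and 43.1% at 3 dpi, against 36.4%, 36.4% and 27.3% of BMP genes, and 27%, 29.8% and 43.1% at 7 dpi, against 10%, 20% and 70%. The fold over the next domain had an interval above 1 for 3, 1 and 0 of the BMP genes at 3 dpi and for 1, 1 and 4 at 7 dpi.

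The target gene ID1, an inhibitor of differentiation that BMP signalling induces, stood at 249.3, 272.2 and 67.1 CPM across the 3 domains at 3 dpi, with its peak window of 5 kept sections at sections 9 to 13. It was 3.72-fold higher on the injury side than on the remote side (2.76 to 4.95), and 2.04-fold under median-of-ratios scaling. ID2 was 4.20-fold higher (2.65 to 6.50), and 2.31-fold under that scaling. ID3 was 1.81-fold higher (1.17 to 2.72) and id2b 1.67-fold (1.2 to 2.27), but these turned to 0.995 and 0.916 under median-of-ratios scaling, and their peak windows were sections 10 to 14 and 12 to 16. The signal transducer gene SMAD1 was highest in the middle, at 45.3, 104.7 and 44.9 CPM, 2.31-fold over the next domain (1.26 to 4.63). Among receptors, BMPR2 was 2.96-fold (1.31 to 6.11; 5 of its 10 injury-side counts in section 9) and acvr1l 2.63-fold (1.42 to 4.61) higher on the injury side, and the metalloprotease gene BMP1, the 1 member of the ligand list with 20 counts, 4.6-fold (1.73 to 11). Under median-of-ratios scaling these were 1.62-fold (0.717 to 3.35), 1.44-fold (0.778 to 2.53) and 2.53-fold (0.951 to 6.11). The receptor genes ACVR2A and ACVR1B (ENSDARG00000052142) stood at 0.576 (0.0671 to 2.24) and 0.377 (0.0445 to 1.43) of their remote-side level on the injury side, and at 0.316 (0.0369 to 1.23) and 0.207 (0.0244 to 0.783) under that scaling. The extracellular modulator HTRA1 was 5.02-fold higher (3.80 to 6.60), and 2.76-fold (2.08 to 3.62) under that scaling.

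At 7 dpi ID1 stood at 175.4, 238.1 and 174.4 CPM, ID3 at 145.3, 60.5 and 60.0 CPM, with 48.3% of its injury-side counts in section 2, without which its fold over the next domain was 1.40, and id2b had 0 injury-side and 191 remote-side counts, at 76.9 CPM on the remote side. HTRA1 stood at 0.285 of its remote-side level on the injury side (0.0917 to 0.676). The follistatin-like gene FSTL1 (ENSDARG00000039576) stood at 1193, 1050 and 1729 CPM, against 241.8, 239.2 and 143.7 CPM at 3 dpi.

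As lists, BMP genes lay inside the matched range for injury-side minus remote-side in both hearts. At 3 dpi the medians were 0.53 for 8 receptor and Smad genes, 0.79 for 6 targets and 0.75 for 3 antagonists, which changed sign to −0.31, −0.07 and −0.11 under median-of-ratios scaling. At 7 dpi they were −0.34 for 4 genes, −0.83 for 5 and −0.54 for 3. In the 7 dpi middle domain against the mean of the others, the 3 antagonists lay outside, at −1.37 (percentile 1.82), but inside with the floor of 3 counts (percentile 3.3), and at 0.10 with the section minimum at 5%. Between 7 and 3 dpi over all sections the receptor and Smad, target and antagonist medians were −0.15, −0.15 and 1.13, and the ligand list had no member with 50 counts in either heart. With the section minimum at 5% of the 75th percentile, the 3 dpi counts were 3 injury-side, 14 middle and 5 remote-side genes.

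**Figure D4:**
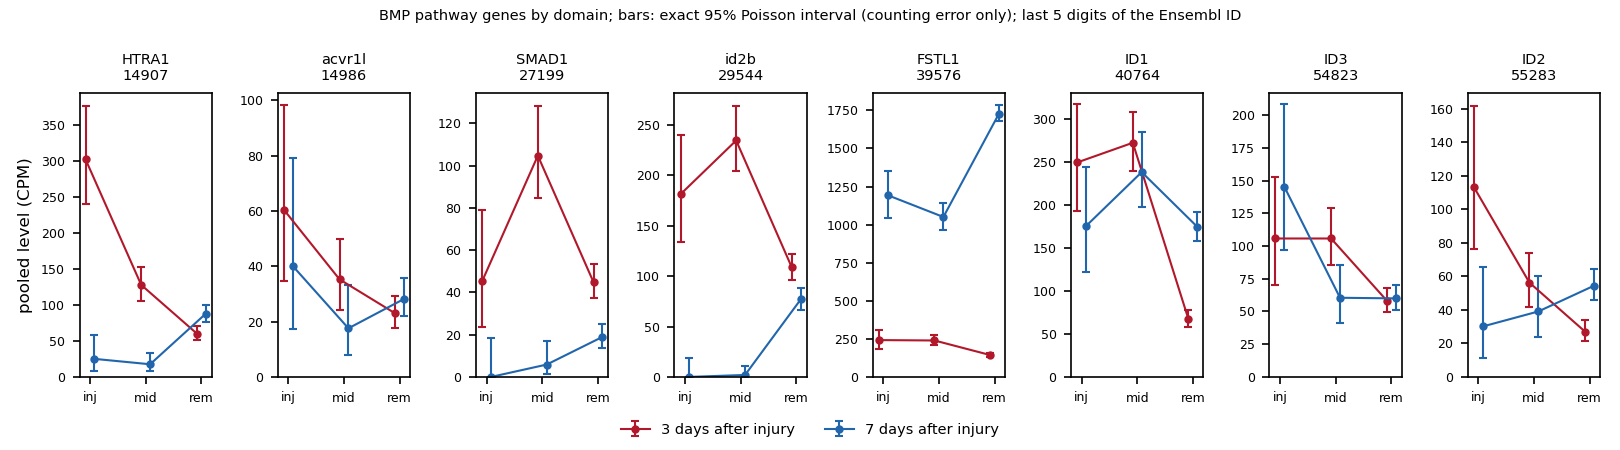
Level in CPM of named BMP pathway genes in the 3 domains of each heart, with 95% Poisson intervals of the counts. At 3 dpi ID1 lay at 249.3, 272.2 and 67.1 CPM and SMAD1 at 45.3, 104.7 and 44.9 CPM; the injury-side excesses of ID3, id2b and FSTL1 at 3 dpi turn under median-of-ratios scaling.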

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

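All tests of explanations in this part were chosen after their result was seen, except the test of NDUFB9 against transcripts of another gene. Section minima of 5% and 40%, domains of equal section number and 4 segments were settings fixed before the data were examined. Median-of-ratios scaling and leaving out the middle domain's edges were fixed then too. The use of that scaling to test an explanation came after its result was seen. Some results differed in sign or direction between the hearts, without a test, since each day had 1 heart and domains of the same name were not the same tissue. In the middle domain against the mean of the others, contractile genes had a median log2 difference of −2.14 at 7 dpi and 0.39 at 3 dpi, stress-responsive cardiomyocyte genes −1.44 and 0.44, and mitochondrial-genome genes −0.66 and 0.36. These differences moved with the sections kept and the domains used: with section minima of 40% and 5% the 7 dpi middle medians were 0.52 and 0.91 for contractile and 0.98 and 1.16 for stress-responsive genes, with 5% 0.11 for mitochondrial-genome genes, and with 3 domains of equal section number the stress-responsive medians were 0.087 at 7 dpi and −0.015 at 3 dpi. The 7 dpi contractile and mitochondrial-genome medians kept their sign with domains of equal section number, with 4 segments and with the middle domain's edges left out. Contractile sums rose from the injury side to the remote side in both hearts. They were 21120, 63290 and 97100 CPM at 3 dpi and 512.2, 919.0 and 22180 CPM at 7 dpi. The opposite contractile signs thus mark where the middle lay between the other domains, not opposite gradients. HTRA1 (ENSDARG00000014907) had an injury-side to remote-side fold of 0.285 (0.0917 to 0.676) at 7 dpi and 5.02 (3.80 to 6.60) at 3 dpi. For id2b (ENSDARG00000029544), with 0 injury-side counts at 7 dpi, the fold was at most 0.195 against 1.67 (1.2 to 2.27) at 3 dpi, and for FSTL1 (ENSDARG00000039576) it was 0.69 (0.603 to 0.786) against 1.68 (1.27 to 2.2). The 3 dpi folds of id2b and FSTL1 were 0.916 and 0.924 under median-of-ratios scaling.

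Data outside the comparisons also held signal. Spike-in RNA held 171 counts at 3 dpi and 8631 at 7 dpi. The 5 sections left out at 3 dpi, with 70293 counts, had a contractile sum of 11200 CPM, and the 14 left out at 7 dpi, with 111570 counts, had 27200 CPM. The last 4 of these, sections 35 to 38, had 46300 CPM from 34064 counts.

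Lists lower at 7 than at 3 dpi were weighed against less myocardium in the sections of the 7 dpi heart. Sections of like contractile level were the middle domain at 3 dpi and remote-side sections at 7 dpi, so place differs along with day. In them the glycolysis median less that of its random lists was 0.35, against −1.23 over all sections, so less myocardium is a candidate explanation of the lower glycolysis list. For oxidative genes the difference was −0.29, against −1.73 over all sections, smaller but still outside the matched range at percentile 0.72, so how far less myocardium accounts for it stays open. For cell cycle genes it was −1.45, against −0.92 over all sections, from 12 members whose median had an interval of −2.23 to 2.78, too wide to decide. Section 34 held 61.3% of the 7 dpi counts in those sections. Without it the medians were −0.52 for glycolysis (percentile 21.64), −0.83 for oxidative (below all 10000 random lists) and −1.47 for cell cycle genes (percentile 5.15). The day itself stays an open explanation, untested with 1 heart per day.

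NDUFB9 and F13A1 stood far apart from genes of related function at 7 dpi. More complex I transcripts would raise the other complex I genes too, but the highest 7 minus 3 log2 ratio among 23 of them was 0.22 and their median −1.65, against 5.41 for NDUFB9, which argues against it. For transcripts of another gene counted under NDUFB9, its injury-side minus remote-side difference at 7 dpi was −0.79, inside the interquartile range of the other complex I genes (−1.81 to −0.48), the outcome set beforehand to count against that explanation; that bound was too loose, because 24.7% of all tested genes lie in that range, so the explanation cannot be told apart from a true difference. More leukocytes at 7 dpi would put about 1550 F13A1 counts on the 3 dpi injury side by its ratio to leukocyte genes, where 1 count was found (upper limit 5.57), which argues against leukocyte number alone. A difference in gene models or counting between the tables, and a difference between the days, stay open and were not tested.

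More genes were higher on the injury side than on the remote side at 3 dpi, 517 against 78. For abundant transcripts that take more of the remote-side counts, median-of-ratios factors gave 133 injury-side and 408 remote-side genes. These factors shift all genes of a domain alike, with the median over all genes going from 0.53 to −0.31, so the turn follows from the scaling and the explanation stays open. Leaving out the top 2 unnamed IDs gave 354 and 125, so those IDs alone are not enough, and this explanation was widened from a few genes to abundant transcripts after that value was seen. Fewer counts in the injury-side domain would let the excess vanish at equal domain totals. Thinned counts gave 567 injury-side and 175 remote-side genes. The remote-side count rose but the excess stayed, which argues against domain totals as the whole of it. Only totals were made equal, and the domains still differed in the number and depth of their sections. Which scaling is nearer to RNA amounts per cell cannot be read from these tables.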

How the results depend on the processing

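Alternatives chosen only after the data were seen were those without section 34, section 1 or the top 2 unnamed IDs, with thinned counts, with levels of at least 3 counts, with sections of like contractile level (also without section 34), and without each gene's top section; the others were set before the data were examined. No paired analysis was possible because there was 1 heart per day. Over all alternatives, 286 summary values stayed within their limits (1.5 times a count, or the interval of a correlation) and 86 moved, and of the list medians and single values 1667 stayed, 181 moved and 20 reversed. A median counts as reversed only where its main value lay outside the matched range. Whatever its place, 173 of 1852 list medians changed sign, 11 of 120 with median-of-ratios factors. Nothing among the summary values moved with totals without mitochondrial-genome and haemoglobin genes or with the edges of the middle domain left out. Those totals left out only the 13 genes of the mitochondrial-genome list and haemoglobin genes found by name. They kept ENSDARG00000080337, the unnamed ID with 20.65% of the 3 dpi counts. Contractile genes were lower and leukocyte genes higher on the injury side of both hearts under each of the alternatives that recompute domain medians, which leaves out sections of like contractile level and each gene's top section. Counts of genes follow the number tested and the pseudocount by construction; for the rest the cause was not tested. The depth limits single genes: few counts in 1 section can make a 2-fold domain gene.

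Counts below are of 2-fold domain genes, in the order injury-side, middle and remote-side where 3 are given, against 517, 39 and 78 at 3 dpi and 177, 331 and 629 at 7 dpi. Shared genes are against 37, with no expected number computed for the alternatives, and r against 0.425. With a gene minimum of 1 count they were 2634, 1315 and 793 at 3 dpi and 1415, 2583 and 2935 at 7 dpi, with 594 shared, r 0.16, 3225 genes higher and 2203 lower at 7 than at 3 dpi, and 10 injury-side and 12 middle lists outside the matched range between days. With a minimum of 200 they were 113, 2 and 32 and then 19, 37 and 225, with 10 shared, r 0.572, 688 genes higher and 537 lower, 7 lists outside for injury-side minus remote-side at 7 dpi and 3 on the injury side between days. With a pseudocount of 10 CPM the 3 dpi counts were 310, 4 and 34, with 23 shared, r 0.461 and 784 genes lower at 7 dpi. Median-of-ratios factors gave 133, 14 and 408 at 3 dpi, 135 shared, 6 BMP genes highest on the remote side at 3 dpi, and ribosomal medians of −0.18 for injury-side minus remote-side and −0.026 for the middle at 3 dpi. The mean of per-section levels gave 59 middle genes at 3 dpi, r 0.348, 3 BMP genes highest in the middle at 7 dpi and a middle ribosomal median of −0.047 at 3 dpi.

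With 4 segments, 3 dpi had 101 middle and 192 remote-side genes, with 87 shared and r 0.512. With 3 domains of equal section number, 3 dpi had 1 middle and 11 remote-side genes and 7 dpi 202 middle genes, with 13 shared, 4 BMP genes highest in the middle and 5 on the remote side at 3 dpi; the 3 dpi endothelial median turned to 0.37, and the middle stress-responsive medians to −0.015 at 3 dpi and 0.087 at 7 dpi. With a section minimum of 40%, there were 49 remote-side genes at 3 dpi and 218 middle genes at 7 dpi, 11 middle lists outside in each heart, 23 shared, r 0.511 and 2 BMP genes highest in the middle at 3 dpi. Reversed medians there were endothelium 0.16 at 3 dpi, and at 7 dpi erythrocyte 0.13, smooth muscle and valve 0.14, middle contractile 0.52 and middle stress-responsive 0.98. With a minimum of 5%, which put 1 to 26 in the 7 dpi injury-side domain, there were 169 middle and 130 remote-side genes at 3 dpi and 565, 551 and 279 at 7 dpi, 127 shared, r 0.557 and 4 middle lists outside between days. BMP genes were then highest in 3, 14 and 5 cases at 3 dpi and 8 in the middle at 7 dpi. Reversed medians were middle ribosome −0.17 at 3 dpi and, at 7 dpi, erythrocyte 0.46, smooth muscle and valve 1.02, and in the middle contractile 0.91, stress-responsive 1.16, glycolysis 0.17, BMP antagonists 0.10 and mitochondrial genome 0.11.

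Thinned counts gave 102 middle and 175 remote-side genes at 3 dpi, 72 shared and r 0.367. Levels of at least 3 counts gave 405 remote-side genes and 8 BMP genes highest on the injury side at 7 dpi, where the floor itself can make a domain of few counts the highest. Without section 1, r was 0.393. Without section 34 there were 214 middle genes at 7 dpi, 23 shared and r 0.314. Without the top 2 unnamed IDs there were 125 remote-side genes at 3 dpi. Without each gene's top section, 224 injury-side and 18 middle genes were left at 3 dpi and 44 injury-side and 91 middle genes at 7 dpi, a loss that the setting makes in part by construction. Sections of like contractile level gave 642 genes higher and 565 lower at 7 than at 3 dpi and a glycolysis median of 0.13. Without section 34 they gave 409 higher, 545 lower and −0.52.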

Other observations

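Growth factor and inflammatory genes held further contrasts at 3 dpi that the list medians do not show. The growth factor binding gene igfbp6b was 8.20-fold higher on the injury side than on the remote side (5.21 to 12.8), and the chemokine gene CXCL12 4.47-fold (3.10 to 6.34), while VEGFA was 4.58-fold higher on the remote side. In the lymphatic and muscle transcription factor gene PROX1, 1 count stood on the injury side against 277 on the remote side, 26.7-fold (4.76 to 1060), and for the cardiac transcription factor gene TBX20 2 counts against 180, 8.69-fold (2.37 to 72.3). JUNB, an early response gene, was 5.66-fold higher on the injury side at 3 dpi (4.71 to 6.78) and stood at 233.3 CPM over the whole 3 dpi ventricle against 1562 CPM at 7 dpi.

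The 2 most abundant unnamed IDs differed between hearts. ENSDARG00000080337 took 9.2%, 18% and 22.6% of counts from the injury-side to the remote-side domain at 3 dpi, and 2.43%, 2.92% and 3.83% at 7 dpi. ENSDARG00000077505 took 0.0185%, 0.014% and 0.0268% at 3 dpi and 11.6%, 10.1% and 5.39% at 7 dpi.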
